A study of Mus musculus with 6 samples.

How the data were processed

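Bulk RNA was measured in 6 mouse leg tumors, 3 per genotype. Per the labels' protocols, tumors were snap frozen, total RNA was extracted with Qiagen RNeasy kits, and libraries were made with Ribo-Zero, which depletes ribosomal RNA and keeps both coding and noncoding transcripts. Novoalign 2.08.03 and the mouse build mm10 are named per the submitters' processing notes, which give no role or order. The authors deposited 1 table of FPKM values, normalized to gene length and library size, with 1 column per tumor, and no column was pooled or belonged to a tumor outside the labels. The counting tool, the gene models, strand handling, the treatment of reads with several matches and the filter that left these 17312 genes are not given in the sources used here. Reads of repeated or near-identical genes, including pseudogenes and small RNA families, and reads of overlapping or antisense genes may therefore have been split or assigned in ways that change their values. FPKM fixes the sum of reads, not of transcripts, so a tumor with many short RNAs has a larger summed FPKM, and a large share of 1 class of RNA lowers all other values in that tumor.

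Each column was matched to a tumor by the sample's own description, and the genotype came from the labels. Gene identifiers were matched to GENCODE mouse release 21 on GRCm38, which mm10 also names, for symbols, positions and gene classes. A symbol was found for 17029 of the 17312 genes and not for 283. Genes with an FPKM of at least 1 in at least 3 tumors were tested, which left 13873.

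Depth was worked out from the steps between low values. A gene's FPKM is a whole number of reads times a step set by its length and the library's total. The totals were set from 1311 genes with a single exon, and between 79.0% and 80.4% of the low values in a tumor came out whole within 0.02 reads. With these totals 17264 of 17312 genes (99.7%) gave whole reads in all tumors, 8737 of them with the length of their annotated exons and 8527 with the smallest whole length that gave whole reads, and 48 did not. Because a smallest length can fit by chance or miss a common factor, recovered reads served only for depth, for floors and intervals of the sex-linked genes, for sums of reads over gene copies and for 1 alternative test. On simulated data with 1500 genes, 99.5% of the read values were returned exactly among the genes that could be recovered. A gene with 0 reads was compared against a floor of 3 reads over the group, and intervals for a ratio of reads were exact binomial intervals at 95% confidence.

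Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), as SS18-SSX2 minus SS18-SSX1, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Means and SDs are of FPKM over the 3 tumors of a genotype, and fold changes are on the log2(FPKM + 1) scale. Gene lists with at least 3 tested members were compared with camera, which asks whether a list's genes move further than other genes, with a preset correlation between genes of 0.01. The same lists were run with camera's estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction, or in either, without comparing them with other genes. Correlations between tumors were Pearson's over tested genes, and the difference within against between genotypes was set against all 10 splits of the tumors into 3 and 3. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Parents of processed pseudogenes were found with blastn 2.17.0 against the annotated protein-coding transcripts of genes in the table (e-value of at most 1e-20, at least 50% of the copy aligned).

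Genes were named by a rule with 6 parts. It took up to 12 called genes per direction with the largest change and no overlap between groups, and filled each direction to 12 with uncalled genes of the smallest p that did not overlap and had a mean of at least 1 FPKM. It also took the genes of the targeted system and 12 markers of the disease and of growth, up to 4 members per list with the smallest p or the highest mean, the 10 genes with the highest mean and the 12 with the largest SD, and the sex-linked genes. The text gives those of most use and summarizes the others. Any other gene is said to have been chosen after its values were seen.

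In data simulated with the depth and spread of these tumors (5 runs, 200 genes changed in each, 13912 tested genes per run), limma called 0.823% of genes changed 2-fold, 39.8% of those changed 4-fold, 69.1% at 8-fold and 85.3% at 16-fold. Of the 519 calls, 41 (7.90%) were genes left unchanged. The simulated genes varied independently of each other, unlike genes in the tumors.

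The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum mean of 5 FPKM, quantile normalization, upper quartile scaling, rescaling to TPM, eBayes without a trend and with robust estimation, weights per tumor (arrayWeights), the tumor number as a block, the mean level of the muscle fibre list as a covariate, each tumor left out in turn, and a further threshold of 2-fold. For the correlations, Spearman's coefficient and the 500 most variable genes were also used. After the data were seen, limma's voom on recovered reads and a fit without both muscle-rich tumors were added. With 1 tumor left out, the spread was pooled over both genotypes.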

Results

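RNA was sequenced from 6 leg tumors of mice that carried a Cre-inducible fusion gene of synovial sarcoma, 3 with SS18-SSX1 and 3 with SS18-SSX2. SS18-SSX is the oncoprotein of synovial sarcoma and joins SS18, a subunit of the BAF (SWI/SNF) chromatin remodelling complex, to the end of an SSX protein. TATCre, a Cre recombinase protein that enters cells, had been placed in the soft tissue in front of the shin, and the tumors were collected about 1 year afterwards. Levels of 17312 genes were given as FPKM, fragment counts scaled to transcript length and to the size of the library. The steps between low values put 13316363, 13767916 and 17546227 reads behind SS18-SSX1 tumors 1, 2 and 3, and 14529847, 7285853 and 14357648 behind SS18-SSX2 tumors 1, 2 and 3. One read in a transcript of 1 kb was therefore worth 0.0570 FPKM in the deepest library, SS18-SSX1 tumor 3, and 0.137 FPKM in the shallowest, SS18-SSX2 tumor 2. Small RNAs and ribosomal RNA took 10.7%, 27.6% and 18.97% of the summed FPKM in the SS18-SSX1 tumors and 7.85%, 31.2% and 18.1% in the SS18-SSX2 tumors, but at most 3.32% of the recovered reads in any tumor. The comparison asks which genes and gene groups differ between tumors driven by the 2 forms of the fusion. The labels do not say that the tumors came from separate mice, so the p-values measure only the spread between these samples.

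Tumors of the same genotype differed widely in the RNA of other cell types. The mean log2(FPKM + 1) of 22 skeletal muscle fibre genes was 8.52 in SS18-SSX1 tumor 2 and 7.24 in SS18-SSX2 tumor 2, against 2.38 to 3.78 in the other 4 tumors. Ckm, the creatine kinase of muscle, stood at 1285 FPKM in SS18-SSX1 tumor 2 and 555 FPKM in SS18-SSX2 tumor 2, and at 7.88 to 69.9 FPKM elsewhere. Mast cell genes were high in SS18-SSX1 tumor 3, where 8 markers averaged 7.14 against 1.27 to 3.21 in the other 5 tumors and the mast cell protease Mcpt4 reached 557 FPKM. Mgp, which encodes a matrix protein that inhibits calcification, ranged from 13.3 FPKM in SS18-SSX1 tumor 1 to 18362 FPKM in SS18-SSX1 tumor 3. Igkc, the constant region of the immunoglobulin kappa chain, reached 671 FPKM in SS18-SSX2 tumor 2 and 71.1 FPKM in SS18-SSX1 tumor 2, with 1.41 to 4.05 FPKM in the rest. Macrophage and monocyte genes averaged 1.92, 3.90 and 3.96 in SS18-SSX1 tumors 1, 2 and 3 and 2.90, 4.46 and 2.79 in SS18-SSX2 tumors 1, 2 and 3.

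Across all 13873 tested genes tumors of 1 genotype were not detectably more alike than tumors of different genotypes. The mean correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.848 over the 6 pairs of tumors of 1 genotype and 0.845 over the 9 pairs of different genotypes. The difference of 0.00307 gave an exact permutation p = 0.4 (one-sided, n = 3 per genotype), where 10 splits of the tumors allow no p under 0.1. The highest correlation was that of SS18-SSX2 tumors 1 and 3, at 0.937, and the next highest joined the muscle-rich tumor 2 of each genotype, at 0.899. The difference turned negative without SS18-SSX2 tumor 1, at -0.0144, and without SS18-SSX2 tumor 3, at -0.0263. The first principal component, with 35.7% of the variance, had SS18-SSX1 tumor 1 and SS18-SSX2 tumors 1 and 3 on its positive side and the other 3 tumors on its negative side. The third component, with 20.6% of the variance, had the genotypes apart, with scores of 49.4, 27.9 and -3.01 for SS18-SSX1 tumors 1, 2 and 3 and -27.9, -13.2 and -33.2 for SS18-SSX2 tumors 1, 2 and 3, where chance alone separates 3 from 3 on a given component in 10% of cases.

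**Figure D1:**
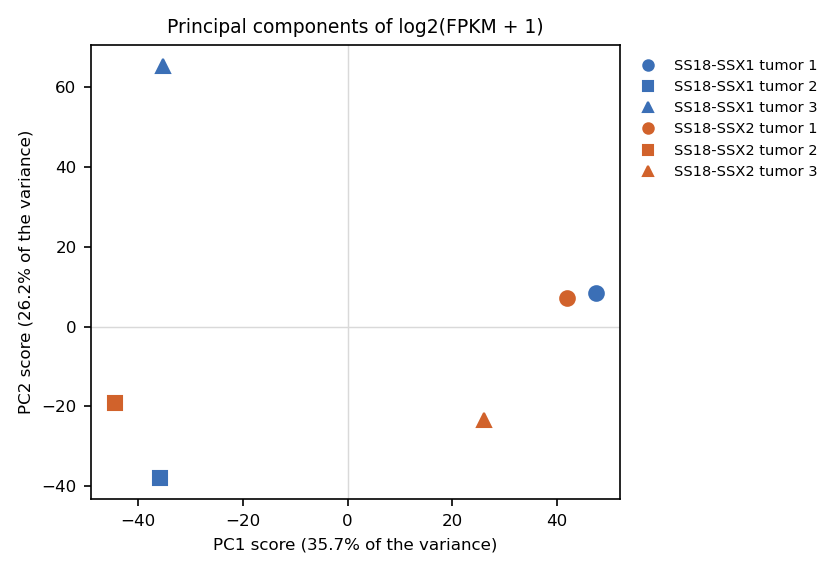
Scores of the 6 tumors on the first principal component (x axis, 35.7% of the variance) and on the second (y axis, 26.2%) of log2(FPKM + 1), unitless, with color for the genotype and marker shape for the tumor number. Tumors of both genotypes lie on either side of 0 on the first axis, with SS18-SSX1 tumor 1 at 47.4 and SS18-SSX2 tumor 1 at 41.9.

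No gene of the targeted system was called between the genotypes, in a test with little power for small changes. Ss18, the mouse gene for the fusion partner, had 25.99 ± 9.16 FPKM in SS18-SSX1 tumors and 25.3 ± 8.42 FPKM in SS18-SSX2 tumors (SD, n = 3), a log2 fold change of -0.02 with SE 0.36 (limma, Benjamini-Hochberg adjusted p = 0.998). How reads from the fusion transcript itself were assigned is not given in the sources used here, so these values cannot be read as those of mouse Ss18 alone. Ss18l1, a paralog of Ss18, had 3.68 ± 2.26 and 3.22 ± 0.760 FPKM. Gt(ROSA)26Sor, the noncoding transcript of a locus often used to place transgenes, had 1.92 ± 1.72 and 1.84 ± 1.19 FPKM. None of these 3 genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.914 for the list).

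Of the 13873 genes tested, 9 differed between the genotypes, 6 higher and 3 lower in SS18-SSX2 tumors, and 4 of the 9 lie on the sex chromosomes. The Y-linked genes Ddx3y, an RNA helicase, and Uty and Kdm5d, members of the histone demethylase families, were expressed in all SS18-SSX1 tumors and nearly absent from all SS18-SSX2 tumors. Ddx3y had 32.8 ± 4.002 FPKM in SS18-SSX1 tumors, Uty 12.4 ± 2.84 and Kdm5d 11.4 ± 2.37 (SD, n = 3). In the SS18-SSX2 tumors together Ddx3y and Uty had 1 read each and Kdm5d had 0. The ratio over depth was 5535 for Ddx3y (95% exact interval 993 to 218653) and 3458 for Uty (620 to 136606), and Kdm5d was at least 749-fold lower, counted against a floor of 3 reads over the group. These intervals and the floor cover counting error only. Xist, the RNA that silences an X chromosome in female cells, had 4.78 ± 1.95 FPKM in SS18-SSX1 tumors and 103 ± 63.5 FPKM in SS18-SSX2 tumors. A further Y-linked gene, Eif2s3y, did not pass (limma adjusted p = 0.525, but 0.0172 without SS18-SSX1 tumor 2, with a range over settings of 0.0172 to 0.99997), with 21.6, 1.38 and 13.4 FPKM in SS18-SSX1 tumors 1, 2 and 3 and 0 reads in each SS18-SSX2 tumor, at least 610-fold lower. The labels do not give the sex of the mice, and high Y-linked expression went with SS18-SSX1 in all 6 tumors, so this pattern and the genotype cannot be separated in any fit.

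The other 5 genes are autosomal and were higher in SS18-SSX2 tumors. Rps3a3 and Gm15772 are annotated as processed pseudogenes, at 98.9% and 99.5% identity to the ribosomal protein genes Rps3a1 and Rpl26, so that the way reads were shared between copies makes both values uncertain. Rps3a3 had 0.635 ± 0.182 FPKM with SS18-SSX1 and 98.7 ± 41.7 FPKM with SS18-SSX2 (SD, n = 3), while Gm15772 had 0.343 ± 0.350 and 34.1 ± 12.8. Tmem59l, which encodes a membrane protein, rose from 1.42 ± 0.829 to 30.9 ± 6.44 FPKM. Lhx5, a LIM-homeodomain transcription factor of the developing forebrain, rose from 0.369 ± 0.272 to 9.49 ± 3.13 FPKM. Acta2, the smooth muscle actin, rose from 4.09 ± 0.874 to 23.6 ± 4.37 FPKM, a ratio of mean FPKM of 5.77.

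**Figure D2:**
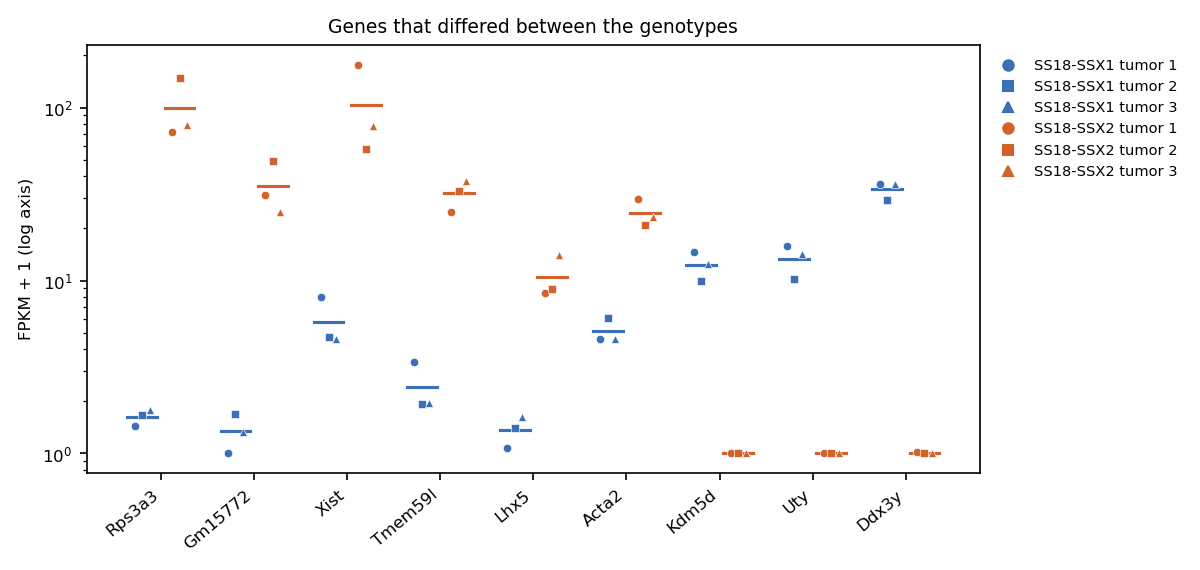
FPKM + 1 on a log axis for the 9 genes that differed between the genotypes, with 1 point per tumor and a horizontal line at the mean of the 3 tumors of a genotype. The 3 points of each genotype lie apart for every gene, and the SS18-SSX2 points of Ddx3y, Uty and Kdm5d lie at or next to 1.

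In limma, log2 fold changes (SS18-SSX2 minus SS18-SSX1, on the log2(FPKM + 1) scale, which understates the change of genes with low values) were 5.86 for Rps3a3 (SE 0.33, adjusted p = 0.000898) and 4.68 for Gm15772 (SE 0.36, adjusted p = 0.00486). They were 4.05 for Xist (SE 0.45, adjusted p = 0.0413), 3.75 for Tmem59l (SE 0.32, adjusted p = 0.0083), 2.92 for Lhx5 (SE 0.33, adjusted p = 0.0442) and 2.27 for Acta2 (SE 0.26, adjusted p = 0.0474). The 3 lower genes had -5.07 for Ddx3y (SE 0.26, adjusted p = 0.000836), -3.72 for Uty (SE 0.29, adjusted p = 0.00486) and -3.61 for Kdm5d (SE 0.28, adjusted p = 0.00486). On GRCm38, Rps3a3 (ENSMUSG00000059751) lies on chromosome 13 from 108670603 to 108671397 and Gm15772 (ENSMUSG00000062353) on chromosome 5 from 3236431 to 3236868. Tmem59l spans 70483867 to 70487358 on chromosome 8, Lhx5 120431699 to 120441223 on chromosome 5, and Acta2 34241090 to 34255590 on chromosome 19. Xist spans 103460366 to 103483254 on chromosome X, and on chromosome Y Ddx3y spans 1260771 to 1286629, Uty 1096861 to 1245759 and Kdm5d 897788 to 956786. Ddx3y, Rps3a3 and Gm15772 kept their calls without each of the 6 tumors in turn. Without SS18-SSX2 tumor 3 only these 3 remained, and Uty (adjusted p = 0.0702), Kdm5d (0.0702) and Tmem59l (0.117) missed the threshold. Lhx5 (adjusted p = 0.0872 to 0.337) and Acta2 (0.0900 to 0.392) missed it whichever tumor was left out, and Xist (0.0367 to 0.238) passed only without SS18-SSX2 tumor 2. Over all 20 other settings adjusted p ranged from 0.00190 to 0.124 for Gm15772, 0.00210 to 0.361 for Uty, 0.00210 to 0.374 for Kdm5d and 0.00216 to 0.117 for Tmem59l. Gm15772 missed the threshold with a pseudocount of 0.1 (0.0522) and with voom (0.124), Uty and Kdm5d with a minimum mean of 5 FPKM, and Tmem59l without both muscle-rich tumors (0.0573). Apart from left-out tumors, Xist passed in 8 of 14 settings, Acta2 in 4 of 14 and Lhx5 in 5 of 13.

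Quantile normalization called 3 genes higher and 3 lower, and rescaling to TPM called 3 higher and 4 lower. Without both muscle-rich tumors, a choice made after the values were seen, 20 genes passed, 14 of them higher, and 6 of the 9 genes were among them. Before adjustment 689 genes had p under 0.05, 452 higher and 237 lower, where chance alone gives 694. The groups did not overlap for 1210 genes, 8.72% of those tested against the 10% that chance gives. In data simulated on these tumors, limma called 39.8% of genes changed 4-fold and 0.823% of those changed 2-fold, so most changes of small size would have been missed.

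Beyond these 9 genes, those with the smallest p whose groups did not overlap did not pass. Among the genes with higher values in SS18-SSX2 tumors, Sulf1, an extracellular heparan sulfate sulfatase, had 40.6 ± 7.82 and 153 ± 34.7 FPKM (SD, n = 3, limma adjusted p = 0.200). Phex, an endopeptidase of bone mineralization, had 0.648 ± 0.870 and 18.5 ± 11.97 FPKM (adjusted p = 0.186). Cnpy1, a gene of the midbrain-hindbrain boundary, had 0.220 ± 0.206 and 7.31 ± 3.93 FPKM (adjusted p = 0.243). Adamtsl1, the antisense transcript 1700006J14Rik and the microRNA gene Mirlet7a-2 each had an adjusted p of 0.172. Among those with lower values, Nell2, a secreted protein of neural tissue, had 42.7 ± 4.41 and 11.9 ± 0.696 FPKM (adjusted p = 0.0765). Clstn3, a synaptic adhesion protein, had 13.1 ± 0.600 and 1.88 ± 1.18 FPKM (adjusted p = 0.172), and the pseudogene Gm8420, a copy of Rpl15, had 12.9 ± 9.03 and 0.113 ± 0.113 FPKM (adjusted p = 0.104). Dusp10, Prkd3, Matn2, Hoxb9, Tma7 and Qpct followed, with adjusted p from 0.353 to 0.413. With weights per tumor Nell2, Gm8420, Cnpy1, Adamtsl1, 1700006J14Rik and Mirlet7a-2 passed (adjusted p from 0.0170 to 0.0495). Cnpy1 (0.0497) and 1700006J14Rik (0.0475) also passed without SS18-SSX2 tumor 2, Gm8420 (0.0323) after rescaling to TPM and Phex (0.0169) with the muscle level as a covariate. The highest adjusted p over settings was 0.534 for Nell2, 0.559 for Gm8420, 0.664 for Phex, 0.833 for 1700006J14Rik and Mirlet7a-2, 0.884 for Adamtsl1 and 0.99997 for Cnpy1.

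Gene groups were compared with camera over 37 lists written before the data were examined, as were the tests, the rule for naming genes and most of the alternative settings. Each list was tested again under 20 other settings (19 for the fusion partner, adipocyte and tendon lists), and ranges of an adjusted p are over these. Of the 31 lists with at least 3 tested members, 11 were called with a preset correlation of 0.01, 7 higher and 4 lower in SS18-SSX2 tumors, and 20 were not. With an estimated correlation camera called 0 lists (2 at an unadjusted p under 0.05, the Notch list and the pericyte and smooth muscle list). The tool fry called 0 in a common direction (2 at an unadjusted p under 0.05) and 1 in either direction, the pericyte and smooth muscle list (adjusted p = 0.000292). The calls below are therefore those of the preset correlation, and 4 of them held without each tumor in turn. Of the 10 splits of the tumors into 3 and 3, 5 called at least 11 lists, the real split among them. A count of 11 is thus not particular to the genotypes, and the paragraphs below describe these tumors.

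Posterior Hox genes, which set position along the body axis and the limb, were lower in SS18-SSX2 tumors as a group. All 16 tested members had a lower mean, with a median log2 fold change of -1.28. Hoxb9 had 21.1 ± 6.18 FPKM with SS18-SSX1 and 2.77 ± 2.24 FPKM with SS18-SSX2 (SD, n = 3), Hoxc10 had 42.9 ± 11.7 and 12.03 ± 7.31, and Hoxc12 had 63.0 ± 22.7 and 13.3 ± 9.39. None of the 16 passed over all genes, and 5 did when adjusted over the list alone, the other two being Hoxc9 and Hoxc11 (Hoxc11 chosen after its values were seen). For the same 5 the groups did not overlap, where chance gives 10% of genes and all tested genes gave 8.72%. The members moved together (estimated correlation 0.758), so the 5 are not independent and cannot be read as an excess. The list was called at camera adjusted p = 1.54e-13 and not with an estimated correlation (adjusted p = 0.466 with an estimated correlation). With the preset correlation it was called in all 20 other settings (adjusted p from 2.36e-22 to 4.28e-05), with medians from -1.90 to -0.78. SS18-SSX1 tumor 3 had a list mean of 2.39, level with the 2.32 and 2.43 of SS18-SSX2 tumors 1 and 3, and the muscle-rich SS18-SSX2 tumor 2 had 0.999.

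**Figure D3:**
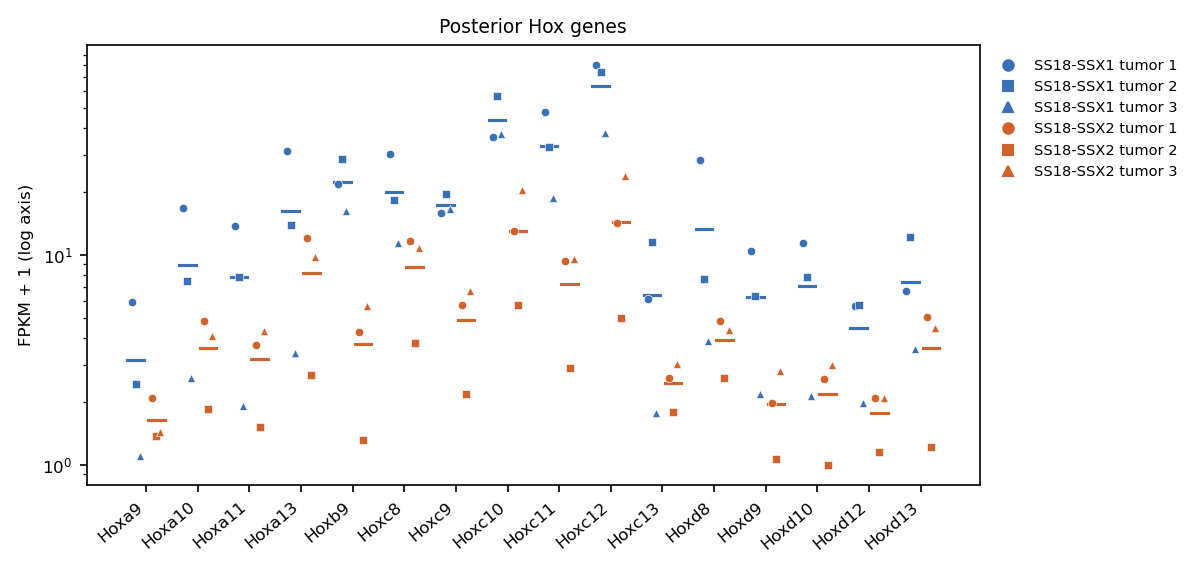
FPKM + 1 on a log axis for the 16 tested posterior Hox genes, with 1 point per tumor and a line at the mean of each genotype. The SS18-SSX2 mean lies below the SS18-SSX1 mean for all 16 genes, and the groups do not overlap for 5 of them.

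Cell cycle genes were higher in SS18-SSX2 tumors as a group, with 29 of 32 members higher, 3 lower and a median log2 fold change of 0.67. Mki67, a marker of proliferating cells, had 15.8 ± 7.56 FPKM with SS18-SSX1 and 47.6 ± 32.2 with SS18-SSX2 (SD, n = 3). Cdc20, an activator of the anaphase-promoting complex, had 11.9 ± 3.07 and 34.1 ± 13.5 FPKM, and the mitotic transcription factor Foxm1 had 4.62 ± 0.542 and 14.7 ± 6.40 FPKM. None of the 32 passed over all genes or adjusted over the list alone, and camera gave adjusted p = 1.80e-09 (adjusted p = 0.814 with an estimated correlation). List means were 3.28, 2.68 and 3.56 in SS18-SSX1 tumors and 4.36, 3.10 and 4.14 in SS18-SSX2 tumors, so the muscle-rich tumor 2 was the lowest of each genotype. The cell cycle median was 0.42 without SS18-SSX2 tumor 1 and 1.05 without SS18-SSX2 tumor 2. Replication-dependent histones, made in S phase, had 19 of 25 members higher and a median of 0.33 (camera adjusted p = 0.00808, adjusted p = 0.843 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Hist1h1b, a linker histone, had 55.4 ± 13.0 and 134 ± 51.0 FPKM. The histone call was lost without SS18-SSX1 tumor 1 (adjusted p = 0.575), SS18-SSX1 tumor 2 (0.0815) or SS18-SSX2 tumor 3 (0.364), with a range of 5.73e-06 to 0.575. The histone median was 0.13 without SS18-SSX1 tumor 2, 0.56 without SS18-SSX1 tumor 3 and 0.07 without SS18-SSX2 tumor 3.

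Targets and ligands of the Notch pathway and targets of Wnt/beta-catenin signaling were also higher in SS18-SSX2 tumors. In the Notch list 11 of 13 members were higher and 2 lower, with a median of 0.92. Hes5, a transcriptional repressor induced by Notch, had 2.33 ± 0.918 FPKM with SS18-SSX1 and 11.1 ± 3.49 with SS18-SSX2 (SD, n = 3), and it passed when adjusted over the list alone but not over all genes (limma adjusted p = 0.353). Jag1, a Notch ligand, had 29.7 ± 10.3 and 55.0 ± 4.14 FPKM, and Hey1, another induced repressor, had 16.2 ± 7.74 and 35.8 ± 12.2. The list was called at camera adjusted p = 8.42e-07 (adjusted p = 0.466 with an estimated correlation) and without each tumor. In the Wnt list 15 of 17 members were higher and 2 lower, with a median of 0.74, and none passed over all genes or adjusted over the list alone. Axin2, a negative regulator induced by the pathway, had 26.005 ± 11.6 and 54.2 ± 9.78 FPKM, Rnf43, a ligase that removes Wnt receptors, 0.825 ± 0.294 and 2.77 ± 0.224, and the Wnt inhibitor Apcdd1 68.5 ± 25.6 and 136 ± 17.5. These 3 are known to restrain the pathway. Camera called the list at adjusted p = 0.000445 (adjusted p = 0.466 with an estimated correlation), and without SS18-SSX1 tumor 1 the median was 0.23 and the adjusted p = 0.0526 (range 2.23e-06 to 0.0526).

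Groups of basement membrane, mural cell and skeletal genes were higher in SS18-SSX2 tumors. Of 17 basement membrane genes 14 were higher and 3 lower, with a median of 0.53, and none passed over all genes or adjusted over the list alone. The laminin chain genes Lama2 (3.39 ± 1.72 and 13.9 ± 6.51 FPKM) and Lamb1 (10.7 ± 1.76 and 25.2 ± 9.35 FPKM, SD, n = 3) did not overlap between genotypes. Camera gave adjusted p = 0.000611 (adjusted p = 0.814 with an estimated correlation), and 0.0846 without SS18-SSX1 tumor 3 (range 1.20e-06 to 0.0846). The basement membrane median was 0.23 without SS18-SSX1 tumor 3 and 1.004 without SS18-SSX2 tumor 2. Of 10 pericyte and smooth muscle genes 8 were higher and 2 lower, with a median of 0.44. Acta2 passed over all genes, and Tagln, an actin-binding protein of smooth muscle with 3.90 ± 1.87 and 12.9 ± 6.20 FPKM, passed with it when adjusted over the list alone. The list had camera adjusted p = 0.00136 (adjusted p = 0.466 with an estimated correlation), and 0.0643 without SS18-SSX1 tumor 3 (range 6.85e-05 to 0.0643). Of 7 cartilage and bone genes 6 were higher and 1 lower, with a median of 0.53, and Phex alone passed when adjusted over the list alone. Col2a1, the collagen of cartilage, had 248 ± 143 and 645 ± 489 FPKM. Camera gave adjusted p = 0.00808 for this list (adjusted p = 0.466 with an estimated correlation), 0.147 without SS18-SSX1 tumor 1 (median 0.33), 0.0551 without SS18-SSX1 tumor 3, 0.0779 with weights per tumor and 0.189 with no filter on low values (range 0.00118 to 0.189).

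Mast cell, skeletal muscle and mitochondrially encoded genes were lower in SS18-SSX2 tumors as groups, and each group was uneven between tumors. All 8 mast cell genes were lower, with a median of -2.68. The proteases Mcpt4 and Cma1 had 557 and 625 FPKM in SS18-SSX1 tumor 3 and between 2.39 and 28.7 FPKM in every other tumor. None of the 8 passed over all genes or adjusted over the list alone. Camera gave adjusted p = 8.42e-07 (adjusted p = 0.621 with an estimated correlation), and without SS18-SSX1 tumor 3 the median was -0.99 with an adjusted p = 3.13e-05 (range 2.05e-11 to 3.13e-05). Of 22 muscle fibre genes 21 were lower and 1 higher, with a median of -1.30 and none past either adjustment (camera adjusted p = 0.00623, adjusted p = 0.843 with an estimated correlation). Tnnt3, a troponin of fast fibres, had 1038 FPKM in SS18-SSX1 tumor 2, 348 FPKM in SS18-SSX2 tumor 2 and 8.21 to 55.7 FPKM in the rest. Without SS18-SSX1 tumor 2 the muscle median was 0.36 and the adjusted p = 0.273, and the call was also lost without SS18-SSX2 tumor 1 (0.429) or tumor 3 (0.265), with a range of 1.04e-23 to 0.597, the highest with the muscle level itself as a covariate. The muscle median was -0.32 and -0.53 without SS18-SSX2 tumors 1 and 3, -2.19 without SS18-SSX1 tumor 1 and -2.82 without SS18-SSX2 tumor 2. Of 8 mitochondrially encoded genes 6 were lower and 2 higher, with a median of -0.54, and none passed over all genes or adjusted over the list alone. The respiratory chain gene mt-Nd2 had 94.8 ± 33.5 and 57.4 ± 18.98 FPKM (SD, n = 3). The list had camera adjusted p = 0.0477 (adjusted p = 0.814 with an estimated correlation) and was called in only 7 of 20 other settings, with 0.0613 at a pseudocount of 0.1 and 0.341 after quantile normalization. It missed the threshold without SS18-SSX1 tumor 2 (0.502) or 3 (0.0551) and without SS18-SSX2 tumor 2 (0.446) or 3 (0.0684), and its median was -0.93 without SS18-SSX2 tumor 1 and -0.29 without SS18-SSX2 tumor 2. Without both muscle-rich tumors camera's direction for the mitochondrial list was higher although its median was -0.30 (adjusted p = 0.825, range 0.000445 to 0.825).

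**Figure D4:**
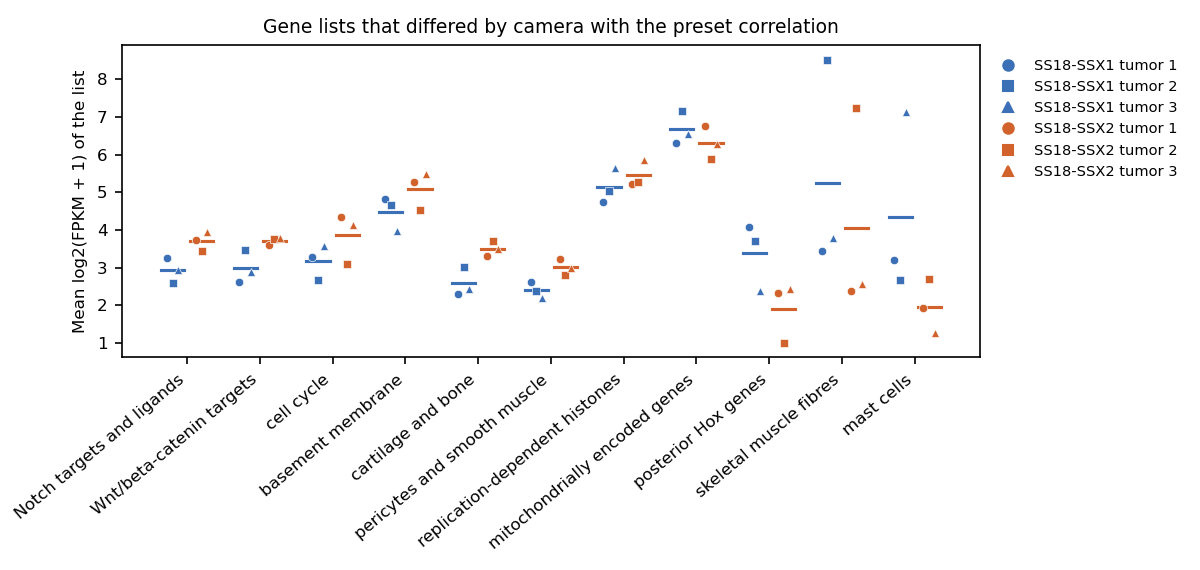
Mean log2(FPKM + 1) per tumor of the 11 lists called by camera with the preset correlation, with 1 point per tumor and a line at the mean of each genotype. Skeletal muscle fibres (8.52 in SS18-SSX1 tumor 2) and mast cells (7.14 in SS18-SSX1 tumor 3) spread most between tumors of 1 genotype.

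Genes tied to the fusion's partners and to the diagnosis of synovial sarcoma were expressed in both genotypes and were not called. Of 27 BAF complex genes 14 were higher and 13 lower, with a median of 0.07 (camera adjusted p = 0.786). The ATPase Smarca4 had 27.3 ± 8.15 FPKM with SS18-SSX1 and 48.6 ± 10.1 with SS18-SSX2 (SD, n = 3), and the core subunit Smarcb1 had 14.1 ± 3.36 and 14.8 ± 1.75. Of 31 Polycomb genes 11 were higher and 20 lower, with a median of -0.11 (camera adjusted p = 0.459). Bmi1, a subunit of the repressive complex that marks histone H2A, was the only one to pass when adjusted over the list alone, at 9.61 ± 2.06 and 2.82 ± 0.958 FPKM. The corepressor Bcor had 66.6 ± 14.5 and 150 ± 40.8 FPKM, the PRC2-associated Phf19 1.19 ± 0.347 and 3.77 ± 0.911, and the methyltransferase Ezh2 8.66 ± 1.58 and 10.6 ± 5.42. Of 24 genes reported high in synovial sarcoma 16 were higher and 8 lower, none past either adjustment, with a median of 0.14, a mean of -0.08 and a camera direction of higher (adjusted p = 0.966). Tle1, a transcriptional corepressor used as a diagnostic marker, had 24.4 ± 1.20 and 34.1 ± 3.81 FPKM, and the survival factor Bcl2 5.18 ± 1.40 and 7.44 ± 3.76. The stem cell transcription factor Sox2 had 36.8 ± 5.05 and 17.0 ± 6.45 FPKM (limma adjusted p = 0.681), the growth factor Igf2 21.1 ± 17.7 and 53.9 ± 54.7, and the homeodomain factor Six4 8.12 ± 1.54 and 2.94 ± 1.38.

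Epithelial and mesenchymal gene groups were not called either, and each had members apart in single tumors. Of 19 epithelial junction and keratin genes 6 were higher and 13 lower, with a median of -0.23 (camera adjusted p = 0.135). Epcam, an epithelial adhesion molecule, had 104 FPKM in SS18-SSX1 tumor 1 and 7.96 to 15.1 FPKM in the other 5. The cadherin Cdh1 had 2.77 ± 1.30 and 2.69 ± 2.66 FPKM (SD, n = 3), the keratins Krt8 7.99 ± 7.80 and 2.47 ± 1.47 and Krt18 17.2 ± 6.46 and 12.2 ± 9.96. Without SS18-SSX1 tumor 2 (adjusted p = 0.0452) or SS18-SSX2 tumor 2 (0.000383) the epithelial list was called lower, as it was in 4 of 20 other settings (range 2.21e-05 to 0.836), while without SS18-SSX1 tumor 1 or SS18-SSX2 tumor 1 its median was 0.01 and 0.04. Of 14 mesenchymal genes and transcription factors of the epithelial-mesenchymal transition 9 were higher and 5 lower, with a median of 0.19 (camera adjusted p = 0.243, 0.00567 without SS18-SSX1 tumor 2, called in 2 of 20 other settings, range 0.00160 to 0.747). The intermediate filament gene Vim had 148 ± 90.5 and 344 ± 96.0 FPKM, and the transcription factor Snai2 11.99 ± 2.53 and 4.14 ± 1.78. Of 21 fibrillar collagen and stromal matrix genes 13 were higher and 8 lower, with a median of 0.24 (camera adjusted p = 0.102, 6.42e-06 without SS18-SSX1 tumor 2, called in 5 of 20 other settings, range 6.42e-06 to 0.745), and the median was -0.17 without SS18-SSX1 tumor 3. Col3a1, a fibrillar collagen, had 141 ± 166 and 688 ± 304 FPKM, and the collagen cross-linking enzyme Lox had 1.90 ± 2.16 and 9.77 ± 7.72. None of the members of these 3 lists passed over all genes or adjusted over the list alone.

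In the remaining signaling and state lists no member passed over all genes or adjusted over the list alone. Hedgehog targets had 5 of 9 members higher, with a median of 0.36 (camera adjusted p = 0.526), and the receptor Ptch1 had 40.6 ± 21.1 and 83.0 ± 41.1 FPKM (SD, n = 3). FGF/MAPK response genes had 9 of 14 higher, a median of 0.06, a mean of 0.01 and a camera direction of lower (adjusted p = 0.682). The MAPK phosphatase Dusp4 had 18.6 ± 8.75 and 8.39 ± 1.16 FPKM. Imprinted growth genes had 8 of 14 higher and a median of 0.11 (camera adjusted p = 0.566). Neuronal genes had 5 of 7 higher and a median of 0.11 (camera adjusted p = 0.526), with 2.65 ± 0.4996 and 11.2 ± 7.22 FPKM for the microtubule protein Map2. Hypoxia and glycolysis genes had 8 of 19 higher and a median of -0.10 (camera adjusted p = 0.682), and the hypoxia-induced Ndrg1 had 10.2 ± 7.13 and 2.88 ± 1.48 FPKM. Immediate early and heat shock genes had 11 of 16 higher and a median of 0.19 (camera adjusted p = 0.682). Interferon response genes had 12 of 14 higher and a median of 0.42 (camera adjusted p = 0.0526), and the signal transducer Stat2 had 11.2 ± 2.86 and 16.5 ± 1.15 FPKM. The interferon list was called without SS18-SSX1 tumor 2 (adjusted p = 0.00157) and without SS18-SSX2 tumor 1 (0.00296) or tumor 3 (0.00139), and in 8 of 20 other settings in all (range 1.34e-05 to 0.981), while its median was -0.08 without SS18-SSX2 tumor 2. Antigen presentation genes had 7 of 15 higher and a median of -0.10 (camera adjusted p = 0.884), but were called lower without SS18-SSX1 tumor 1 (adjusted p = 0.0122) or SS18-SSX2 tumor 2 (0.0272), with a range of 0.0122 to 0.965 and medians from -0.68 to 0.36.

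Markers of other cell types showed no further called difference. Endothelial genes had 10 of 16 higher and a median of 0.35 (camera adjusted p = 0.459), and were called higher without SS18-SSX1 tumor 1 (adjusted p = 0.0184) or SS18-SSX2 tumor 2 (0.00258) and with weights per tumor (0.00720), with a range of 0.00258 to 0.941, while the median was -0.07 without SS18-SSX1 tumor 2. The endothelial cadherin Cdh5 had 13.4 ± 12.5 and 23.7 ± 15.5 FPKM (SD, n = 3). Macrophage and monocyte genes had 10 of 15 higher and a median of 0.22 (camera adjusted p = 0.764), and without SS18-SSX1 tumor 1 they were called lower, with a median of -0.50 (adjusted p = 0.00809, range 0.00809 to 0.905). With the muscle level as a covariate they were called higher, with a median of 0.47 (adjusted p = 0.0344). The lysosomal protein Cd68 had 5.32 ± 2.18 and 6.82 ± 1.61 FPKM. Erythroid genes had 5 of 5 higher and a median of 0.60 (camera adjusted p = 0.526, 0.00515 without SS18-SSX1 tumor 3, 0.0300 with weights per tumor, range 0.00515 to 0.787), with medians from -0.25 to 1.69. Adipocyte genes had 2 of 4 higher and a median of -0.32 (camera adjusted p = 0.682). Tendon genes had 3 of 6 higher, a median of 0.07, a mean of -0.03 and a camera direction of lower (adjusted p = 0.682), and the tendon differentiation marker Tnmd had 4.04 ± 3.09 and 0.899 ± 0.592 FPKM. No member of these 5 lists passed over all genes or adjusted over the list alone. The lists for myogenic progenitors (2 tested members), neutrophils (2), T and NK cells (1), B and plasma cells (0), epidermis (2) and Schwann cells (2) had too few members for camera. Among these, Pax7, a transcription factor of muscle stem cells, passed when adjusted over the 2 tested myogenic members alone, at 4.79 ± 2.64 and 13.4 ± 6.04 FPKM. It did not pass over all genes or over the 24 genes reported high in synovial sarcoma, a list that also holds it.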

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

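The fits with voom on recovered reads and without both muscle-rich tumors were chosen only after the results were seen. Of 1827 combinations of 92 tested genes named in the text with the other settings, 1733 kept direction and side of the threshold, 52 lost a call, 14 gained one and 28, in 8 genes, changed direction. For the 31 tested lists 520 of 617 combinations kept both, 25 lost a call, 27 gained one and 45, in 15 lists, turned the median. Here too the 25 could come only from the 11 called lists. The lists of X-linked, forebrain and midbrain, and anterior Hox genes kept their direction in all 20 settings each. Of the scalings, TPM put the median log2 fold change of all genes furthest from 0, at 0.0841 against 0.00955 as deposited.

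The count of 9 genes was 5 with a pseudocount of 0.1, 16 (11 higher, all 9 among them) with weights per tumor, 20 without both muscle-rich tumors, and 3 to 11 with 1 tumor left out, fewest without SS18-SSX2 tumor 3. Apart from the replicate block, the other settings gave 6 to 9. The count of 11 lists was 0 with an estimated correlation, 0 with fry and 8 to 13 with 1 tumor left out, and 10 to 13 in the other settings. The correlation difference of 0.00307 ran from -0.0263 to 0.0211 with 1 tumor left out, below 0 at -0.0144 and -0.0263 without SS18-SSX2 tumors 1 and 3. It was 0.0257 without both muscle-rich tumors (exact permutation p = 0.333, the smallest that 4 tumors allow) and 0.0535 over the 500 most variable genes (exact permutation p = 0.3). The estimated correlation within the 11 called lists was 0.0732 to 0.974, above the preset 0.01, which widens the error of a list's mean. Fry makes no comparison with other genes, but whether that accounts for its count was not tested. For the other shifts the cause was not tested either.

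The tumor numbers recur in both genotypes, and so do the first letters of the column names, N for number 1, A for number 2 and B for number 3. No label says what the numbers or letters mark. Deviations of same-numbered tumors from their genotype means had correlations of 0.38, 0.31 and -0.28 for numbers 1, 2 and 3, so those of number 3 ran in opposite directions. The numbers were not taken to pair the samples, but a batch shared by same-lettered tumors is not excluded. With the number as a replicate block 4 genes and 11 lists were called. Ddx3y, Rps3a3, Gm15772 and Xist passed, and Uty (adjusted p = 0.0613), Kdm5d (0.0613), Tmem59l (0.0974), Lhx5 (0.119) and Acta2 (0.310) missed the threshold. Of the lists called without it, 10 were called with it, and SS18-SSX1 tumors 1 and 2, but not 3, correlated best with their own number.

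Single genes that changed direction were not called in any setting. Log2 fold changes were 0.01005 for Ss18 and -0.0428 for Gt(ROSA)26Sor after quantile normalization, 0.0550 for Ss18 and 0.00127 for Ss18l1 after rescaling to TPM, and 0.11 for Ss18, -0.0123 for Gt(ROSA)26Sor and -0.74 for Igkc with weights per tumor. Gt(ROSA)26Sor had -0.10 with the muscle covariate and -0.68 without both muscle-rich tumors, where Smarcb1 had -0.0235. With 1 tumor left out the lowest and highest were -0.33 and 0.19 for Ss18, -0.26 and 0.30 for Ss18l1, -0.52 and 0.50 for Gt(ROSA)26Sor, -0.75 and 0.11 for Cdh1, -0.18 and 0.56 for Ezh2, -0.0192 and 0.25 for Smarcb1, -0.0718 and 5.09 for Mgp, and -0.63 and 3.34 for Igkc. The cause was not tested.

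List medians turned to -0.0916 (FGF/MAPK), 0.13 (hypoxia), 0.31 (antigen presentation), 0.00462 (skeletal muscle, itself the covariate) and -0.00368 (endothelium) with the muscle covariate. They turned to -0.0546 (collagens), -0.31 (macrophages) and -0.25 (tendon) with weights per tumor, 0.0803 (hypoxia) and -0.0400 (macrophages) without both muscle-rich tumors, 0.0550 (fusion partner) after rescaling to TPM, -0.0530 (tendon) after quantile normalization, 0.13 (adipocytes) with no filter and -0.0141 (BAF) with a minimum mean of 5 FPKM. With 1 tumor left out medians ran from -0.33 to 0.30 (fusion partner), -0.0141 to 0.12 (BAF), -0.70 to 0.0394 (epithelial), -0.17 to 1.05 (collagens), -0.12 to 0.15 (FGF/MAPK), -0.14 to 0.21 (hypoxia), -0.0827 to 0.76 (interferon), -0.68 to 0.36 (antigen presentation) and -0.22 to 0.43 (immediate early). Uncalled lists whose median moved by over 1.5 times without turning ran from -0.13 to -0.0213 (Polycomb, nearest 0 without SS18-SSX1 tumor 3), 0.000293 to 0.32 (genes reported high in synovial sarcoma, without SS18-SSX1 tumors 3 and 1), 0.0375 to 0.57 (Hedgehog, without SS18-SSX2 tumors 3 and 2), 0.0617 to 0.29 (imprinted, highest without SS18-SSX1 tumor 2), 0.00813 to 0.34 (neuronal, without SS18-SSX1 tumor 3 and SS18-SSX2 tumor 2) and 0.0776 to 0.51 (mesenchymal, without SS18-SSX1 tumors 3 and 2). For cell types medians ran from -2.82 to 0.36 (skeletal muscle), -0.59 to 0.14 (adipocytes), -0.0717 to 0.71 (endothelium), -0.50 to 0.53 (macrophages), -0.25 to 1.49 (erythroid) and -0.35 to 0.82 (tendon). The cause was not tested.

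Depth limits single low values: 1 read in a transcript of 1 kb was worth 0.137 FPKM in SS18-SSX2 tumor 2 and at most 0.0751 FPKM in the other 5 tumors.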

Other observations

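The lists of forebrain and midbrain, anterior Hox, limb and X-linked genes, and the tests of sex, of pseudogene parents and of the muscle covariate for the Hox genes, were chosen only after the results were seen.

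A list of genes that pattern the forebrain and midbrain of the embryo was written around Lhx5, Cnpy1 and others already seen to differ, so its values are a description and no test of the group. Of 17 tested members 16 had a higher mean in SS18-SSX2 tumors and 1, Lhx2, a lower one, with a median log2 fold change of 1.12, and all genes named here were chosen after their values were seen. En2, a homeodomain factor of the midbrain-hindbrain boundary, had 1.70 ± 2.21 FPKM with SS18-SSX1 and 18.2 ± 3.12 with SS18-SSX2 (SD, n = 3, limma adjusted p = 0.297), with 4.22 FPKM in SS18-SSX1 tumor 3 and 0.0754 in SS18-SSX1 tumor 1. Lhx1, a LIM-homeodomain factor, had 4.74 ± 1.66 and 13.4 ± 1.93 FPKM. Pax6, Otx2 and Vax1, transcription factors of the eye field and forebrain, had 0.127 ± 0.0971, 0.116 ± 0.108 and 0.255 ± 0.258 FPKM with SS18-SSX1 and 2.19 ± 0.291, 2.97 ± 2.23 and 5.73 ± 3.55 with SS18-SSX2. Over 20 other settings the median lay between 0.72 and 1.52, with 0.72 both without SS18-SSX1 tumor 2 and with no filter on low values. En2 passed with weights per tumor (adjusted p = 0.0317) and without SS18-SSX1 tumor 3 (0.0335), with a range of 0.0317 to 0.99997. Over all genes only Lhx5 passed.

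Hox genes outside the posterior list had lower means in SS18-SSX2 tumors as well. This list was written after the posterior Hox genes were seen to be lower and holds their neighbors in the same clusters. Its values are therefore a description and no test of the group. All 15 tested anterior and central members were lower, with a median log2 fold change of -1.42. Over 20 other settings the median lay between -1.93 and -0.88. Of the 31 tested Hox genes in the 4 clusters, 13 did not overlap between genotypes, 7 of 8 in the Hoxb cluster, 6 of 9 in Hoxc, 0 of 8 in Hoxa and 0 of 6 in Hoxd. Over all tested genes the share was 8.72%, where chance gives 10%. Hox genes moved together, so these counts are not of independent genes and cannot be read as an excess over that share. Hoxb6 and Hoxb7, chosen after their values were seen, had 13.7 ± 1.99 and 4.60 ± 0.162 FPKM with SS18-SSX1 and 2.95 ± 2.43 and 1.09 ± 0.868 with SS18-SSX2 (SD, n = 3). The Hoxa mean of log2(FPKM + 1) was 3.39, 2.18 and 0.900 in SS18-SSX1 tumors 1, 2 and 3 and 1.75, 0.599 and 1.49 in SS18-SSX2 tumors 1, 2 and 3. The limb identity list, with 3 tested members, had a camera p of 0.605.

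Sex-linked genes separated the genotypes in all 6 tumors. The pattern of the other genotype was seen in 0 tumors, which restates this separation, so that a mislabelled tumor was neither tested nor excluded. The values argue against mice of the same sex in both genotypes. Xist had 3.58 to 7.03 FPKM in SS18-SSX1 tumors and 56.3 to 175 FPKM in SS18-SSX2 tumors. The Y-linked genes together had 47.8 to 85.2 FPKM with SS18-SSX1 and at most 0.0238 FPKM with SS18-SSX2. That is the pattern of males for SS18-SSX1 and of females for SS18-SSX2, though the labels do not give the sex. The 6 tested X genes that escape inactivation were all higher in SS18-SSX2 tumors. Their median log2 fold change was 0.49, with a camera p of 0.000219 (p of 0.0685 with an estimated correlation). Kdm5c, the X-linked counterpart of Kdm5d, had 25.98 ± 7.74 and 58.7 ± 10.6 FPKM (SD, n = 3, limma adjusted p = 0.593). Whether sex or the form of the fusion goes with the 5 autosomal calls cannot be told apart, since the patterns coincide in every tumor.

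The 2 called processed pseudogenes may hold reads of their parents, a technical explanation, or differ through a strain variant, which was not tested. Among 246 pseudogenes tested with their parents, the parent moved the opposite way for 8 of 14 (57.1%) at an unadjusted p under 0.05 and for 108 of 232 others (46.6%), a one-sided Fisher's exact p of 0.310, which decides nothing with so few. The 8 include Rps3a3 and Gm15772 themselves, which prompted the test, so the higher share is in part their own. In CPM of recovered reads, Rps3a3 had 0.549 with SS18-SSX1 and 85.3 with SS18-SSX2, while its parent Rps3a1 had 77.6 ± 29.2 and 26.3 ± 1.61, and their sum was 78.1 ± 29.4 and 112 ± 36.0 (SD, n = 3). For Gm15772 and its parent Rpl26 the sum was 130.03 ± 67.3 and 59.0 ± 18.2, with 0.179 and 17.8 in the copy. Reads shared with the parent therefore stay open for both, as does the fusion form, and Rps3a1 and Rpl26 were chosen after their values were seen.

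The lower posterior Hox genes in SS18-SSX2 tumors were weighed against 3 technical explanations, each of which would bring the median log2 fold change of -1.28 to within 0.3 of 0. With the muscle level as a covariate it was -1.46, the scaling nearest to 0 gave -1.27 and the left-out tumor nearest to 0 (SS18-SSX2 tumor 2) gave -0.99. All were beyond a bound of -0.64, which had itself been taken from the observed median. No 1 tumor therefore accounted for the whole shift, although the median was -0.78 without both muscle-rich tumors. Each genotype had 1 muscle-rich tumor, so the covariate could hardly have taken up the difference and does not decide on muscle content. The scalings left the median of all genes between -0.0155 and 0.0841, so none could have removed a shift of -1.28. They show only that the shift did not depend on which of them was used. The 10 splits of the tumors are too few for a share under 0.05: 3 gave a median as far from 0, with 1.28 for the real split. Splits that mixed the genotypes gave 1.46 and 1.53, so a shift of this size was not particular to the genotypes. Also open are the fusion form, the sex of the mice and the place or cell in which a tumor began.

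For the count of genes, 1 of the 10 splits called as many as the 9 of the real split, which is the real split itself, and the highest other called 0. Only the real split also parts the tumors by Y-linked expression and Xist, and 4 of the 9 genes lie on the sex chromosomes. Its lead therefore cannot be put down to the fusion form, and 10 splits are too few for a share under 0.05. For the gene lists 5 of the 10 splits, the real one among them, called at least the real 11, and the highest other called 19. A count of 11 called lists was therefore not particular to the genotypes.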
